A study of Ginkgo biloba with 2 samples.

How the data were processed

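The samples were mature ovules and fully expanded leaves of female ginkgo trees (*Ginkgo biloba*), harvested in 2012. Per the labels' protocols, tissue was frozen in liquid nitrogen and kept at -80 °C, total RNA came from a modified CTAB extraction, and libraries followed the standard Illumina procedure. There was 1 library per tissue, so there are no replicates, and every difference below compares these 2 libraries and not the tissues in general. No p-value or standard error was computed, and the intervals on read counts below speak only for these 2 libraries.

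Per the file headers, the authors deposited for each library the count of uniquely mapped reads on each reference sequence, the sequence's length, and the percent of its bases covered by reads. Per the file headers, the authors also gave an RPKM value, which is reads per kilobase of sequence and per 1000000 uniquely mapped reads. Each row further carried gene ontology terms and the description of the best BLAST hit in the nr protein database. The assembler, aligner, their versions and the BLAST threshold are not given in the sources used here. The title speaks of an integrated de novo assembly, and no reference genome was used here. Tested on the tables, the read column summed to the total in its header in both libraries, and RPKM equalled reads divided by length and total in every row to a relative tolerance of 1e-06. A sequence listed for 1 library alone therefore had 0 reads in the other. The reference held 58436 sequences whose identifiers mark them as assembled and 6079 sequences taken from GenBank, mostly expressed sequence tags. The identifiers of the assembled sequences end in a tag that names ginkgo leaf, and whether the assembly came from leaf RNA is not stated in the sources used here.

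The depth was 4581771 uniquely mapped reads in ovule and 4245222 in leaf. Sequences with 1 read had 49 bases covered, so reads were 49 bases long. A floor of 3 reads, the number that a count of 0 allows, corresponded to an RPKM of 0.655 in ovule and 0.707 in leaf for a sequence of 1000 bases. Folds between the libraries were taken from reads per 1000000 (RPM) with an exact Clopper-Pearson 95% interval on the 2 read counts. Intervals and floors cover counting error only, and neither the spread between trees nor amplification duplicates. Where 1 library had 0 reads, the fold was computed against 3 reads in that library and is written as a lower bound. This bound leaves out the counting error of the other library, so the lower limit of the counting interval is smaller.

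The comparison used log2((RPKM in ovule + 0.5)/(RPKM in leaf + 0.5)) for sequences with an RPKM of at least 1 in 1 or both libraries. This scale understates the difference of weakly expressed sequences. A sequence was called higher in a tissue at an absolute log2 ratio of at least 1. Gene lists were 26 sets of text patterns on the descriptions, covering pathways, regulators, tissue markers and control genes. Each list is described by the median log2 ratio of its members with an order-statistic 95% interval, by the number of members called each way, and by its reads summed over members. A sequence whose description matched a pair of steps was counted in both, which held for 13 antenna and photosystem II sequences, 1 flavonoid sequence and levopimaradiene synthase. Lists could also share sequences, such as Unigene48300 in the cell wall and xylem lists and Unigene13864 in the storage and cuticle lists. Sums were also taken without the member with the most reads per 1000000 over both libraries, called the most-read sequence. The median was set against 10000 random lists of the same size, matched on mean log2 expression in 20 bins, and a list stands apart where its percentile was under 2.5 or over 97.5. Random lists were drawn from all sequences past the filter, with or without a description. Of 24 lists with at least 5 members, chance would put 1.2 outside these bounds if members were independent draws from that pool. List members all carry a description, and several can be fragments or copies of 1 gene. A percentile therefore does not separate a list from described sequences in general, and 1.2 may be too low. Because a ratio against 0 reads is a bound, the list medians were also computed with such sequences at 3 reads in the empty library and never past no difference.

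Genes were named by a rule. It took the 10 described sequences with the largest ratio in each direction at an RPKM of at least 10 in the higher tissue, and the 5 most abundant described sequences per library. It also took, for each list, the 2 members with the highest mean RPKM and the largest called member in each direction. For each step of the flavonoid and terpenoid pathways it took the most abundant sequence. Sequences described as unknown, hypothetical, predicted or uncharacterized proteins were left out of the first 2 parts. The rule gave 123 sequences, and those that matter most are printed. GenBank sequences are named by description alone. Measures, thresholds, lists, the rule and 15 alternatives were set before the data were examined. After seeing the data, 4 alternatives were added, and the species name in each description was removed before the patterns were applied, because a pattern for the gene REVOLUTA had matched the cycad *Cycas revoluta*. The list of microbial and animal species was still matched against the species name.

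Many genes were spread over several reference sequences, and reads were kept only where they mapped uniquely. Near-identical copies lose reads this way, so the level of a single sequence is uncertain wherever its description is shared, and 1 description often stood for both fragments and copies of a gene. The alternatives covered the pseudocount, the filter on low values, the scaling between libraries, sequence length, sequences with reads in both libraries, and RPKM summed per description. They also covered the call threshold, the counting interval, the detection threshold, and the total behind each list's share of RPKM. The scripts were tested on simulated data: reads for all 64515 sequences were drawn from the real levels and depths, and 53003 of these passed the expression filter. Among simulated changes the 2-fold call recovered 40.8% of 49 sequences at 2-fold, 91.8% of 49 at 4-fold, 94.0% of 50 at 8-fold and 100% of 49 at 16-fold. Counting noise alone put 22.2% of unchanged sequences past the 2-fold call, 1.14% when the counting interval also had to exclude 1, and 3.13% among sequences with an RPKM of at least 10. Of 200 random lists without a difference, 7.00% fell outside the percentile bounds.

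The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 for the TMM scaling factors alone.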

Results

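Messenger RNA levels were compared between mature ovules and fully expanded leaves of female *Ginkgo biloba*, with 1 sequencing library per tissue. The ovule library held 4581771 uniquely mapped reads on 50240 reference sequences, and the leaf library 4245222 reads on 58121. Together they covered 64515 sequences, of which 43846 had reads in both, 14275 in leaf alone and 6394 in ovule alone. At an RPKM of at least 1, 41255 sequences were detected in ovule and 50421 in leaf. Depth per sequence was low: the median listed sequence had 8 reads in ovule and 5 in leaf, and 8915 and 11089 sequences rested on a single read. A description that names a function was attached to 11385 sequences, which took 29.4% of the ovule reads and 27.2% of the leaf reads. No BLAST hit was recorded for 28141 sequences.

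The design asks how transcript levels in ovules differ from those in leaves. Some gene lists stood apart from matched random lists. Among those higher in ovule were DNA replication and cell division (median log2 ratio of ovule over leaf 2.10, 99 sequences), the cell wall list (2.07, 56 sequences) and flavonoid genes (2.05, 67 sequences). Among those higher in leaf were photosynthetic light reactions (-1.0, 52 sequences) and defence proteins (-0.81, 67 sequences). An extensin-3-like cell wall protein (Unigene342) reached an RPKM of 7456 in ovule against 7.16 in leaf, 1041-fold higher (95% counting interval, 566 to 2172). A pathogenesis-related protein 1 (CL7229.Contig1) stood at 4.14 in ovule and 3263 in leaf, 789-fold higher in leaf (530 to 1231). Of 56768 sequences past the expression filter, 15522 (27.3%) were called higher in ovule and 19921 (35.1%) higher in leaf. Which tissue had more calls depended on the low counts. With a counting interval that also excluded 1, 9794 were higher in ovule and 7703 in leaf, and at an RPKM of at least 10 the calls were 8299 and 3928 of 19844. Ovule took 43.8% of all calls in the main comparison, 60.5% at an RPKM of at least 5, 62.1% at 20 or more reads, and 56.1% among sequences with reads in both libraries. TMM scaling moved the median log2 ratio of all sequences from -0.10 to -0.24, and rescaling to TPM moved it to -0.25, so ratios close to 0 carry no direction.

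The sequences with the largest ratios toward ovule included wall and surface proteins. An early nodulin from GenBank had 12011 ovule reads and 3 leaf reads, a 3710-fold difference (1269 to 17991), and a cytochrome P450 had 1980 and 1, an 1835-fold difference (329 to 72497). A fasciclin-like arabinogalactan protein (Unigene48300), of a family of cell surface glycoproteins, had 1103 and 2 reads, a 511-fold difference (141 to 4225). Several wall-related sequences had no leaf reads at all. An LRX1-like leucine-rich repeat extensin with 640 ovule reads was at least 198-fold higher in ovule, and a xyloglucan endotransglucosylase/hydrolase 9-like sequence with 418 reads at least 129-fold. An expansin, a protein that loosens walls, was at least 74.1-fold higher, and a second xyloglucan enzyme (Unigene42024) at least 46.6-fold.

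Toward leaf, the sequences with the largest ratios included lectins and defence-type proteins. A mannose-binding lectin from GenBank had 2 ovule and 7158 leaf reads, a 3863-fold difference (1069 to 31902), and a jacalin-related lectin (Unigene6626) had 3 and 3351, a 1206-fold difference (412 to 5849). A dirigent protein (CL3076.Contig1), of a family that steers the coupling of phenolic radicals, was 1188-fold higher in leaf (328 to 9814), and an endochitinase (Unigene15954) with 1 ovule read was 1072-fold higher (192 to 42373). A calcium-binding CML25-like protein (Unigene23874) was 2188-fold higher (392 to 86451), and a RING-H2 finger protein (Unigene23910) 494-fold (211 to 1523). Among the most abundant sequences, catalase (Unigene6522), which breaks down hydrogen peroxide, had an RPKM of 192 in ovule and 2003 in leaf. A glycine-rich RNA-binding protein (CL3003.Contig1) was abundant in both, at 1946 and 4780. A Clp protease proteolytic subunit (Unigene18965) went the other way, at 4968 in ovule and 1449 in leaf.

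Flavonoid genes were on balance far higher in ovule. Of 67 sequences, 41 were higher in ovule, 12 in leaf and 14 under 2-fold, and their summed reads were 5.27-fold higher in ovule. The median log2 ratio was 2.05 (95% interval, 0.70 to 2.73), above all 10000 matched random lists, and 1.51 with empty libraries set at 3 reads. Chalcone synthase, which makes the flavonoid skeleton, had 5411 ovule and 545 leaf reads over 7 sequences, a 9.20-fold difference (8.42 to 10.1), and its member Unigene25696 had 2013 and 4. Flavonol synthase was 16.4-fold higher in ovule (13.5 to 20.1), with Unigene13025 at an RPKM of 259 against 18.3. Anthocyanidin synthase was 42.2-fold higher (28.0 to 66.8) and anthocyanidin reductase, which leads to proanthocyanidins, 15.6-fold higher (13.3 to 18.3), with Unigene15457 at 719 against 37.9. Flavanone 3-hydroxylase was 6.69-fold higher (5.10 to 8.91), leucoanthocyanidin reductase 3.01-fold (2.44 to 3.72) and phenylalanine ammonia-lyase, the entry enzyme, 2.01-fold (1.84 to 2.20). Cinnamate 4-hydroxylase was the exception: 6 of its 8 sequences were higher in leaf and its reads were 1.92-fold higher there (1.70 to 2.17), or 1.10-fold with an interval that includes 1 (0.921 to 1.30) without its most-read sequence. For dihydroflavonol reductase the counts were 16 and 3, a 4.94-fold difference (1.41 to 26.5). Flavonoid 3'-hydroxylase had 6 and 10 reads, a difference not detectable at this depth. No sequence past the filter matched the patterns for 4-coumarate-CoA ligase or chalcone isomerase. Without the most-read sequence of each step, the ovule excess was 5.82-fold for chalcone synthase, 29.0-fold for flavonol synthase, 5.86-fold for anthocyanidin reductase, 14.8-fold for leucoanthocyanidin reductase and 6.17-fold for phenylalanine ammonia-lyase, and for dihydroflavonol reductase 3 and 1 reads remained. The list no longer stood apart with RPKM summed per description (median 0.64, percentile 90.2) or among assembled sequences alone (0.53, percentile 96.7).

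**Figure D1:**
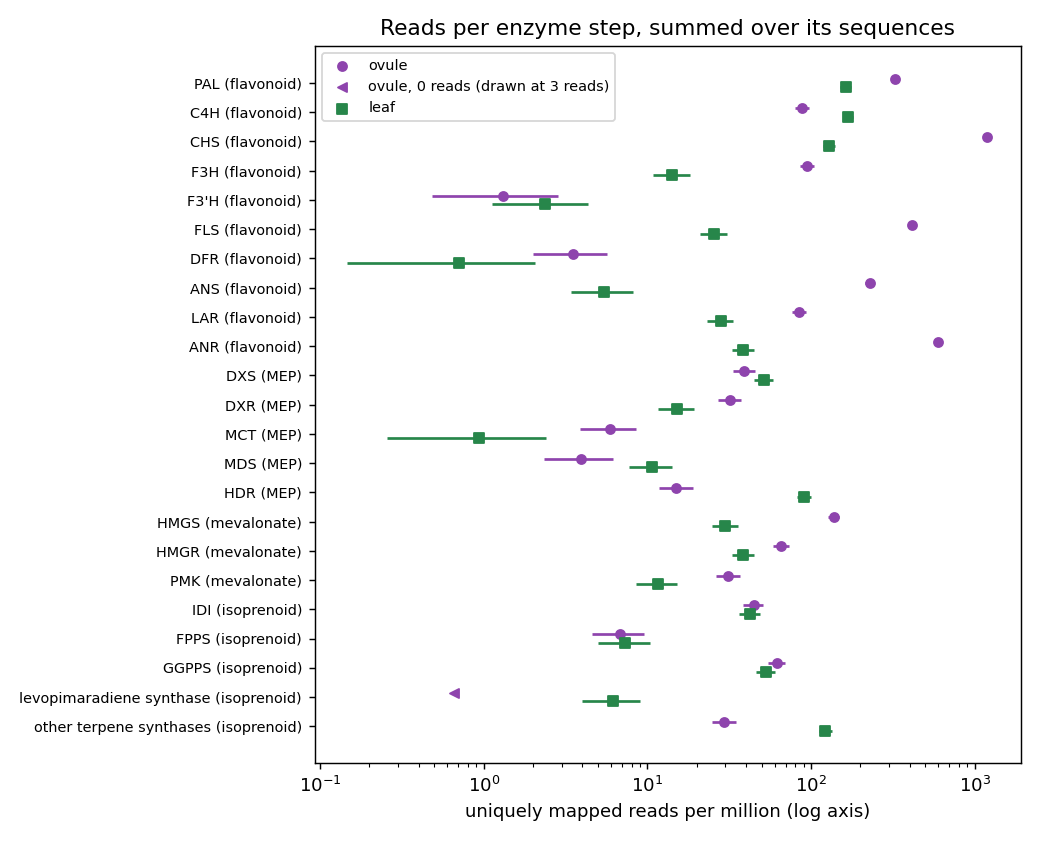
Uniquely mapped reads per 1000000 (RPM, log axis) for each enzyme step of the flavonoid, MEP, mevalonate and isoprenoid lists, summed over the sequences of the step, in the ovule library (circles) and the leaf library (squares). Lines are exact Poisson 95% intervals for counting error, and the triangle marks 0 reads drawn at 3 reads. Levopimaradiene synthase is counted in the other terpene synthases as well, and 1 sequence in both flavanone 3-hydroxylase and flavonol synthase. Chalcone synthase had the most ovule reads of any step, 1181 RPM against 128 in leaf.

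Terpenoid genes, which in ginkgo lead to the ginkgolides, were followed by pathway, with no test of the pathways against each other. Sequences of the cytosolic mevalonate route leaned to ovule: 7 of 10 were higher there and 3 in leaf, with summed reads 2.94-fold higher (1.94-fold without HMG-CoA synthase). The median was 1.91 with an interval that spans 0 (-2.25 to 3.79; percentile 99.8), or 1.5 with the empty library at 3 reads. HMG-CoA reductase made up 8 of the 10, so the list mainly reflects this enzyme. Patterns for acetoacetyl-CoA thiolase, mevalonate kinase and mevalonate diphosphate decarboxylase matched no sequence past the filter. HMG-CoA synthase (Unigene20259) had 632 and 127 reads, 4.61-fold higher in ovule (3.81 to 5.62), and phosphomevalonate kinase (Unigene992) was 2.70-fold higher (1.94 to 3.82). HMG-CoA reductase sequences pointed both ways, 5 to ovule and 3 to leaf, with summed reads 1.71-fold higher in ovule (1.41 to 2.08), or 1.24-fold without the most-read copy (0.995 to 1.54). One reductase copy (Unigene49103) had 56 ovule and 2 leaf reads and a GenBank copy 2 and 57, so the split between copies is uncertain. The list for the plastid MEP route did not stand apart (14 sequences, median -0.52, -2.41 to 1.03; percentile 17.9), and its patterns for the enzymes CMK and HDS matched no sequence past the filter. The deposited gene ontology term for this mevalonate-independent route, examined after the results were seen, held 219 sequences and lay toward leaf (median -0.37, -0.65 to -0.18), below all 1000 matched random lists. With 219 sequences against 14, the term holds many that are not on the enzyme list, so it gives no direction for the enzymes. The last enzyme of the MEP route, HDR, was 6.02-fold higher in leaf over 4 sequences (4.65 to 7.90), with CL6601.Contig1 at 29 and 283 reads, and 2.75-fold without that contig (1.89 to 4.07). DXR (Unigene19516) was 2.11-fold higher in ovule (1.57 to 2.88) and MCT (CL6445.Contig2) 6.25-fold (2.18 to 24.6), while MDS (Unigene24218) was 2.70-fold higher in leaf (1.53 to 4.95). Isopentenyl diphosphate isomerase, farnesyl diphosphate synthase and geranylgeranyl diphosphate synthase differed by at most 1.17-fold, each with an interval that included 1. Levopimaradiene synthase (CL1121.Contig1), which forms the diterpene precursor of ginkgolides, had 0 ovule and 26 leaf reads and was at least 9.35-fold higher in leaf. These reads covered 14.45% of the contig, and 3 reference sequences share its description, so the level of the gene is uncertain. The step of other terpene synthases, whose 12 sequences include levopimaradiene synthase, was 4.16-fold higher in leaf (3.43 to 5.06). Most of this came from a bisabolene synthase (CL5139.Contig1) with 9 and 351 reads, and without it the difference was 1.45-fold (1.14 to 1.84). A farnesene synthase (CL3618.Contig1) went the other way, with 57 and 4 reads. The isoprenoid list as a whole had a median of 0.12 (20 sequences, percentile 67.6), and this median was -0.03 under TMM scaling and -0.04 after rescaling to TPM.

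Photosynthesis genes were higher in leaf, though by modest ratios. Of 52 light-reaction sequences, 26 were higher in leaf, 2 in ovule and 24 under 2-fold. The median was -1.0 (-1.36 to -0.61; percentile 0.23), or -0.77 with empty libraries at 3 reads, and the list took 0.672% of the RPKM in leaf and 0.223% in ovule. Light-harvesting antenna proteins, which capture light for the photosystems, were 3.11-fold higher in leaf over 26 sequences (3.02 to 3.20), with Unigene6444 at an RPKM of 1816 against 476. The 7 photosystem I sequences were 4.20-fold higher in leaf (3.87 to 4.56). Electron carriers were 12.7-fold higher in leaf (10.8 to 15.1), but 1 of their 3 sequences (Unigene10920, singled out after its values were seen) carried this, the other two were under 2-fold, the median was -0.61, and the difference was 1.46-fold without it (1.02 to 2.11). Reads on photosystem II were 1.28-fold higher in ovule (1.23 to 1.32), although 11 of its 29 sequences were higher in leaf and 2 in ovule. Of the 29, 13 are antenna proteins counted in both groups. Most of those ovule reads, 4721 of 6783, came from a single psbI contig (CL3265.Contig1, singled out after its values were seen), where they covered 7.57% of its bases. Without this contig the direction turned, and reads on the other 28 sequences were 1.63-fold higher in leaf (1.54 to 1.72), and 1.78-fold (1.62 to 1.94) over the 15 that are not antenna proteins. For carbon fixation, 15 of 26 sequences were higher in leaf and 5 in ovule, with a median of -1.12 (-1.91 to -0.08; percentile 1.96). Rubisco activase, which keeps the carbon-fixing enzyme active, was 19.6-fold higher in leaf (17.4 to 22.2). The small subunit of Rubisco had few reads in either tissue, 825 in ovule and 574 in leaf over 17 sequences past the filter, and 1 description was spread over 43 reference sequences, so its level is uncertain. The carbon fixation list did not stand apart without the expression filter (percentile 26.6) or under TMM scaling (percentile 3.50). Organelle-encoded transcripts had a median near 0 (-0.08, 25 sequences, percentile 41.3), while their summed reads were 4.45-fold higher in leaf, mostly from an NAD(P)H-quinone oxidoreductase subunit M (Unigene23879), which plants encode in the nucleus, with 278 and 2130 reads. Without it the summed reads were 1.61-fold higher in leaf (1.41 to 1.84). Some plastid-encoded sequences outside this list went the other way. Examples were the psbI contig above, a psbA contig (Unigene12325) with 321 ovule and 114 leaf reads, and whole chloroplast genome sequences (431 and 218 RPM). Sequences whose description names no genome were not sorted by origin. Among these was the Clp protease subunit Unigene18965, with 22559 ovule and 6095 leaf reads. Plastid-encoded sequences were not examined as a set, so the list gives no direction for them.

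**Figure D2:**
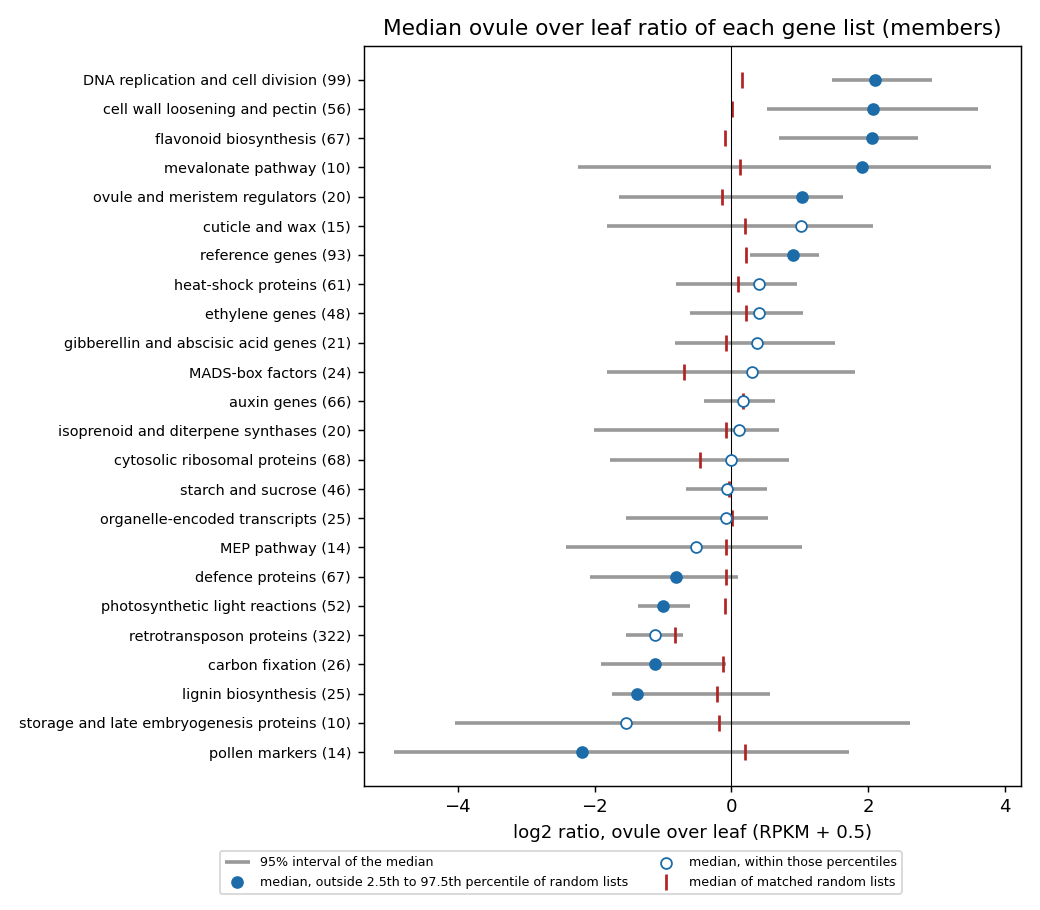
Median log2 ratio of ovule over leaf (RPKM + 0.5) of each gene list with at least 5 members, with order-statistic 95% intervals as lines and member numbers in brackets. Filled points fall outside the central 95% of matched random lists, whose median is the vertical mark. DNA replication and cell division lies at 2.10 and photosynthetic light reactions at -1.0.

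Genes of DNA replication and cell division were higher in ovule. Of 99 sequences, 70 were higher in ovule, 9 in leaf and 20 under 2-fold, with summed reads 4.96-fold higher. The median was 2.10 (1.47 to 2.93), above all matched random lists, and 1.52 with empty libraries at 3 reads. Replication proteins such as MCM helicases and PCNA were 10.4-fold higher over 22 sequences (9.32 to 11.7). Histones were 4.62-fold higher (4.41 to 4.84), cyclins 4.19-fold (3.63 to 4.84; 1.98-fold without the most-read sequence) and kinesins and other mitotic proteins 3.73-fold (3.43 to 4.05). A histone H1-like sequence (Unigene6466) had an RPKM of 591 in ovule and 102 in leaf, and a GenBank histone H3.2 had 2691 and 2 reads, a 1247-fold difference (345 to 10299). Genes often used as references were not level either. Of 93 actin, tubulin, elongation factor and ubiquitin sequences, 42 were higher in ovule, 15 in leaf and 36 under 2-fold, with a median of 0.90 (0.28 to 1.29; percentile 99.97). A beta-tubulin from GenBank had 497 and 1 reads, whereas an alpha-tubulin (CL1384.Contig1) was 2.26-fold higher in leaf (2.13 to 2.41). Polyubiquitin (CL124.Contig11) had an RPKM of 483 and 451.

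Regulators of reproductive development held large contrasts in single genes. GbMADS8, a ginkgo MADS-box factor, had 1012 ovule reads and 1 leaf read, a 938-fold difference (168 to 37072), and GbMADS10 had 186 and 1, a 172-fold difference (30.6 to 6843). In number the MADS-box list nevertheless went both ways: 11 of 24 sequences were higher in ovule and 11 in leaf. Those in leaf included an SVP-like factor (Unigene11388) with 0 and 11 reads. With a counting interval that excluded 1, the calls were 9 and 7, and 15 sequences had at most 1 read in 1 or both libraries. Summed reads of the list were 9.36-fold higher in ovule (7.98 to 11.0), or 3.77-fold without GbMADS8 (3.17 to 4.49). The median of the list was 0.31 (-1.82 to 1.81, percentile 94.4), and -1.76 among assembled sequences alone. An AINTEGUMENTA-like factor, of a family that promotes ovule and organ growth, had 275 ovule reads and none in leaf, at least 84.9-fold higher. The 3 AINTEGUMENTA and related AP2 sequences together were 7.28-fold higher in ovule (5.59 to 9.62). All 63 of their leaf reads lay on CL3837.Contig1, and without it the counts were 282 and 0. KNOX and BELL homeobox sequences went both ways: 3 of 9 were higher in ovule and 2 in leaf, with a median of 0.67. Their summed reads were 1.23-fold higher in leaf (1.14 to 1.33), but 1.67-fold higher in ovule (1.52 to 1.83) without the BEL1-like CL1070.Contig2, which was 8.68-fold higher in leaf (7.07 to 10.7). Another BEL1-like sequence, Unigene7276, was 2.46-fold higher in ovule (1.96 to 3.11). WUSCHEL-related sequences had 10 and 0 reads, at least 3.09-fold higher in ovule against 3 reads, with a counting interval that starts at 2.08-fold. Class III HD-Zip sequences leaned to leaf in number, 4 of 6 against 2 in ovule (median -2.05), on 25 ovule and 19 leaf reads. Without the most-read sequence, 5 and 16 reads remained, 3.45-fold higher in leaf (1.21 to 12.1). The list of 20 ovule and meristem regulators, 10 higher in ovule and 6 in leaf, had a median of 1.03 (-1.64 to 1.64; percentile 98.2), or 0.66 with empty libraries at 3 reads. Among assembled sequences alone it was 0.16 (percentile 63.5).

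The list of cell wall loosening and pectin genes lay toward ovule, with 33 of 56 sequences higher there and 18 in leaf. The median was 2.07 (0.52 to 3.60), above all matched random lists, although summed reads were only 1.20-fold higher because a xyloglucan enzyme (CL3005.Contig3) had 5263 leaf reads against 52 in ovule, and 3.69-fold higher without it. An arabinogalactan-like protein (Unigene45432) stood at an RPKM of 1795 in ovule and 6.76 in leaf. All 4 sequences of the xylem and secondary wall list were higher in ovule, with summed reads 10.8-fold higher (fasciclin-like proteins such as Unigene49679, 314 and 3 reads). The sum was 5.78-fold higher without Unigene48300, which is on the cell wall loosening list as well, so the lists are not separate. Lignin genes leaned to leaf: 13 of 25 were higher there and 5 in ovule, with a median of -1.38 (-1.75 to 0.57; percentile 1.57). That median was -0.64 with empty libraries at 3 reads. Cinnamoyl-CoA reductase and cinnamyl alcohol dehydrogenase, which make the lignin monomers, were 2.91-fold higher in leaf (2.58 to 3.30), and a laccase (Unigene25503) was 43.7-fold higher (11.7 to 367). The deposited gene ontology term for lignin biosynthesis, examined after the results were seen, had a median of 0.81 (31 sequences, percentile 95.1). The lignin list fell back within the random lists with a pseudocount of 0.1 (percentile 3.35) or 1 (percentile 5.30). Cuticle and wax genes went both ways, 8 of 15 to ovule and 5 to leaf (median 1.02, percentile 95.5). A lipid transfer protein from GenBank was 95.1-fold higher in ovule (32.2 to 464) and a WAX2-like protein (CL4440.Contig2) 4.54-fold higher in leaf (4.14 to 4.98).

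Defence proteins took 0.823% of the RPKM in leaf (0.450% without the most abundant sequences of the libraries, the pathogenesis-related protein 1 among them) and 0.116% in ovule, and their summed reads were 11.5-fold higher in leaf, or 5.49-fold without that protein. Of 67 sequences, 31 were higher in leaf, 17 in ovule and 19 under 2-fold, with a median of -0.81 (-2.07 to 0.09; percentile 0.34), or -0.30 with empty libraries at 3 reads. A few sequences carried the sum: the pathogenesis-related protein 1 above and a class IV chitinase (CL2419.Contig2), with 331 and 10939 reads, 35.7-fold higher in leaf (32 to 39.9). A ginkgo defensin, by contrast, had 294 ovule reads and none in leaf, at least 90.8-fold higher in ovule, though 10 sequences share its description and its level is uncertain. The list did not stand apart among sequences of at least 500 bases (median -0.30, percentile 12.6). The 14 sequences described as pollen proteins had a median of -2.18 with an interval that spans 0 (-4.94 to 1.73; percentile 0), with 8 higher in leaf and 5 in ovule. These were mainly homologues of pollen allergens, of which CPA63-like Unigene15769 had 11 ovule and 1459 leaf reads and an isoform of allergen No.121 (Unigene16909) 1602 and 34. Storage and late embryogenesis proteins were few in both tissues (10 sequences, median -1.54, percentile 4.05). A basic 7S globulin (Unigene15477) had 12 and 232 reads, and a late embryogenesis abundant protein (Unigene28313) 57 and 6.

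The remaining lists did not stand apart from matched random lists. Auxin genes had a median of 0.18 (66 sequences, percentile 50.3) against summed reads 1.35-fold higher in leaf, where a dormancy/auxin-associated protein (Unigene6452) had an RPKM of 1181 against 249. Without it the summed reads were 1.38-fold higher in ovule (1.34 to 1.42). Gene ontology terms, examined after the results were seen, stood apart toward ovule for auxin polar transport (median 0.86, 68 sequences, percentile 99.7) and auxin mediated signaling (0.71, 65 sequences, percentile 98.3). Gibberellin and abscisic acid genes had a median of 0.37 (21 sequences, percentile 78.8), again opposite in sign to the summed reads, with a gibberellin 20-oxidase (Unigene11329) 4.92-fold higher in leaf (3.86 to 6.35), without which the summed reads were 1.14-fold higher in ovule (1.02 to 1.27). Ethylene genes had a median of 0.40 (48 sequences, percentile 77.2) and even summed reads, 938 RPM in ovule and 961 in leaf. Leaving out CL3668.Contig1, the most-read sequence, made the sum 1.22-fold higher in ovule (1.17 to 1.28). Heat-shock proteins had a median of 0.41 (61 sequences, percentile 87.0) and a mean of -0.15, with the HSP80-like CL5202.Contig5 at an RPKM of 1207 in ovule and 420 in leaf. Starch and sucrose genes had a median of -0.07 (46 sequences, percentile 45.9) and a mean of 0.05. Among them a sucrose synthase (CL4329.Contig1), which cleaves imported sucrose, was 9.97-fold higher in ovule (9.02 to 11.0), a cell wall invertase (Unigene33626) 34.5-fold higher in ovule (14.5 to 107), and a soluble starch synthase (Unigene24343) 4.16-fold higher in leaf (3.83 to 4.52). Cytosolic ribosomal proteins had a median of -0.01 (68 sequences, percentile 91.7) and a mean of -0.20, although their summed reads were 1.64-fold higher in ovule, or 2.52-fold without the most-read sequence. Their median was 1.84 at an RPKM of at least 5 and -1.72 among assembled sequences alone. Retrotransposon proteins had a median of -1.12 (322 sequences, percentile 5.38), where matched random lists had -0.82, and it became 0.00 with empty libraries at 3 reads. Of these sequences 165 were higher in leaf and 54 in ovule, or 51 and 10 with a counting interval that excluded 1. Their summed reads were 1.94-fold higher in leaf (1.85 to 2.04), and 2.11-fold without the most-read sequence. The list of microbial and animal species matched no description past the filter, which does not exclude reads from such species.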

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

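The tests in this part were chosen after the results were seen. The column for covered bases entered no comparison, and it set 2 abundant contigs apart. Reads on the psbI contig CL3265.Contig1, of 2760 bases, lay on 7.57% of its length in ovule (4721 reads on 209 bases) and on 7.50% in leaf (1817 reads on 207 bases). On a GAST1-like contig of 2402 bases, CL5553.Contig1, the 2057 leaf reads lay on 4.66% of the length, or 112 bases, against 6 reads in ovule. Reads were also found on 4 whole chloroplast genome sequences, which no gene list used: 1976 in ovule and 925 in leaf, or 431 and 218 RPM.

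Sequences on the photosynthesis lists took few leaf reads. The light-reaction list held 25845 leaf reads (6088 RPM) and 0.672% of the leaf RPKM. A set of 43 sequences described as the same Rubisco small chain held 599 leaf and 817 ovule reads. Only sequences whose description matched a pattern were counted, and descriptions that name a function took 27.2% of the leaf reads. Photosynthesis sequences that the patterns missed therefore stay open as a reason for the low total. An exchange of the 2 libraries is argued against by the light-reaction list itself, whose median log2 ratio of ovule over leaf was -1.0 (-1.36 to -0.61). Loss of reads that map to several near-identical sequences stays open as well and cannot be told apart from a low level in these leaves. Members whose description was on 5 or more reference sequences had 0.486 times the median leaf RPKM of the others (3.91, interval 1.82 to 6.34, over 34 sequences, against 8.05, interval 3.32 to 34.2, over 44), and the intervals overlap. No biological explanation was tested, since both tissues entered as 1 library each.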

How the results depend on the processing

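Of the tests in this part, those with at least 20 reads, with assembled sequences alone, with the species name searched and without the most-read member of a sum were chosen after the results were seen. No paired analysis was possible because there was 1 library per tissue. Some lists kept their direction and stood apart from matched random lists under every alternative run. Toward ovule these were DNA replication and cell division (medians 1.52 to 2.80), the cell wall list (1.10 to 3.44), the mevalonate pathway (1.34 to 2.41) and reference genes (0.65 to 1.14). Toward leaf they were light reactions (-1.20 to -0.77) and pollen proteins (-3.09 to -0.88). In the mevalonate list, 8 of 10 sequences in the main comparison were HMG-CoA reductase. For the lists not named here the cause was not tested, except that a filter leaves fewer sequences. Depth limits single sequences: 22.2% of unchanged simulated sequences passed the 2-fold call, and 3.13% at an RPKM of at least 10.

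Calls in ovule and leaf were 9794 and 7703 with the counting interval, 7149 and 10867 at a log2 ratio of 2, 6191 and 6237 at 500 bases, and 8223 and 5012 at 20 reads. Leaf calls were 7141 at an RPKM of 5 and 8752 with reads in both libraries, and ovule calls 9405 with RPKM summed per description. At an RPKM of 5, 23778 ovule and 22306 leaf sequences were detected.

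The lignin median no longer stood apart with a pseudocount of 0.1 (-1.39) or 1 (-0.98), without a filter (-0.57), at an RPKM of 5 (-0.64), with reads in both (-0.64), at 500 bases (-1.41) or at 20 reads (-0.64). Carbon fixation did not without a filter (-0.61), under TMM (-1.26) or TPM (-1.19) scaling, with totals lacking the 10 most abundant sequences (-1.16), at 500 bases (-1.48) or summed per description (-1.16). Ovule and meristem regulators did not at an RPKM of 5 (1.28), with reads in both (1.03), at 20 reads (1.03) or with assembled sequences (0.16), and their median was -0.10 with the species name searched. Flavonoid genes did not when summed per description (0.64) or with assembled sequences (0.53), and defence proteins did not at 500 bases (-0.30).

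Ribosomal proteins came to stand apart without a filter (0.62), at an RPKM of 5 (1.84), with reads in both (1.19), at 500 bases (1.44) and at 20 reads (1.86), and toward leaf with assembled sequences (-1.72). Retrotransposon proteins did with a pseudocount of 0.1 (-1.45), without a filter (-1.08), at 500 bases (-1.58) and at 20 reads (-0.61). Storage proteins did at an RPKM of 5 (-1.84), with reads in both (-1.26), at 20 reads (-1.81) and with assembled sequences (-1.87). The MEP pathway did at an RPKM of 5 (-1.24), heat-shock proteins without a filter (0.57) and MADS-box factors at 500 bases (1.09).

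Summing RPKM per description turned 5 named sequences: a Rubisco small chain to -0.054, cinnamate hydroxylase Unigene6655 to 0.28, an HMG-CoA reductase to 2.49, a ribosomal protein L10 to -1.05 and reverse transcriptase CL2409.Contig6 to -1.87. Leaving out the most-read member turned the log2 ratio of summed reads to 0.46 for auxin, 0.19 for gibberellin and abscisic acid, -0.71 for starch and sucrose, -0.70 for photosystem II, -0.37 for the Rubisco small subunit, 0.11 for DXS, -1.92 for C3H and HCT and 0.74 for KNOX and BELL. It also turned sums whose full interval had included no difference, to 0.29 for ethylene, -1.79 for class III HD-Zip and -0.30 for isopentenyl diphosphate isomerase. Shares of RPKM (in percent) shifted when the 10 most abundant sequences of each library, 19 in all, left both the total and the lists, where 1 was a defence protein. In ovule and leaf they became 0.229 and 0.705 for light reactions, 0.459 and 0.0615 for flavonoids, 0.547 and 0.0993 for cell division, 0.365 and 0.219 for ribosomal proteins, and 0.457 and 0.354 for heat-shock proteins. They became 0.163 and 0.256 for auxin, 0.0841 and 0.0864 for ethylene, 0.634 and 0.196 for cell walls, 0.122 and 0.110 for starch and sucrose, and 0.377 and 0.305 for reference genes. In leaf alone they became 0.319 for carbon fixation, 0.0514 for cuticle, 0.450 for defence, 0.230 for pollen proteins, 0.182 for retrotransposons and 0.0905 for organelle transcripts.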

Other observations

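The gene ontology comparison and the tests in this part were chosen after the results were seen, apart from the length test of a leaf-derived reference, which was set before its result. The deposited gene ontology terms gave a second view of the libraries, over 632 terms with at least 30 sequences past the filter, each set against 1000 matched random lists. Of these, 268 terms lay above the central 95% of the random lists and 75 below it. The random lists were drawn from all 56768 sequences past the filter, of which 20594 carried any term. A sequence can carry several terms. These counts therefore do not separate a process from annotated sequences in general, and the terms are not independent of each other. Control of the G2/M transition had a median log2 ratio of 2.87 (37 sequences), DNA replication initiation 2.81 (50), cell proliferation 2.61 (116) and spindle assembly 2.48 (42). Also above the random lists were histone H3-K9 methylation (1.72, 131 sequences), DNA methylation (1.38, 111), embryo sac development (1.52, 70) and floral organ formation (1.47, 68), where 48 sequences were higher in ovule and 2 in leaf. Several other developmental terms did not stand apart, among them ovule development (0.05, 100 sequences, percentile 15.3), flower development (0.16, 100, percentile 33.5), carpel development (0.32, 34, percentile 68.0) and embryo development ending in seed dormancy (0.38, 384, percentile 92.7).

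Threonine-type endopeptidase activity, the proteasome core, had a median of 1.75 (33 sequences), proteasome assembly 1.47 (58), the nuclear pore 1.21 (58, with 35 higher in ovule and 0 in leaf), sterol biosynthesis 1.36 (104) and fatty acid biosynthesis 1.5 (109). Structural constituents of the ribosome had a median of 1.12 over 391 sequences, where the description-based ribosomal list of 68 sequences had -0.01. Some terms, but not every related one, also differed from the lists of similar name: auxin polar transport had 0.86 (68 sequences), basipetal auxin transport 1.18 (36), gibberellic acid signaling 1.09 (33) and the response to abscisic acid 0.50 (337), all above the random lists, while starch biosynthesis had -0.62 (193), below them. Toward leaf, catabolism of light-harvesting complex II had a median of -1.76 (34), divalent metal ion transport -1.41 (39), plastoglobules, the lipid bodies of chloroplasts, -1.35 (80), the response to blue light -1.33 (88) and chlorophyll catabolism -1.16 (58). Chloroplast thylakoid membrane sequences had a median of -0.84 (369). The term for the mevalonate-independent pathway of isopentenyl diphosphate biosynthesis had -0.37 (219 sequences, against 14 on the MEP enzyme list).

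The reference sequences themselves differed by origin. Expressed sequence tags from GenBank whose identifiers start with EX, DR and CB had median log2 ratios of 1.59 (2190 sequences), 1.61 (813) and 1.72 (284), those starting with GE -0.73 (549), and assembled sequences -0.17 (52827). More sequences had reads in leaf alone (14275) than in ovule alone (6394), an excess of 7881. Most of these held few reads, 1 or 2 in 62.3% of the leaf-only and 61.4% of the ovule-only sequences, and with 10 reads or more there were 1080 and 945. A difference in depth is argued against: the ovule library was the deeper, by 336549 reads. So is concentration of the ovule reads, since the share of reads on the 100 most abundant sequences was lower in ovule, by a difference of -6.27 percentage points. A candidate explanation is a reference assembled mainly from leaf RNA (the identifiers of assembled sequences end in a tag that names leaf): among GenBank sequences with reads in 1 library 29.1% were leaf-only (27.5 to 30.8), against 76.0% (75.3 to 76.6) among assembled ones, though the GenBank tags may themselves come from particular tissues, and a true tissue difference was not tested.

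At an RPKM of at least 10, assembled sequences higher in ovule were shorter, with a median length of 499 bases against 868 for those higher in leaf. Over all calls the medians were 294.5 and 285 bases. Counting noise on short sequences is argued against, since at an RPKM of at least 50 and 100 reads the gap was 369.5 bases (bootstrap interval, 277 to 439.5). A leaf-derived reference could leave ovule transcripts in fragments, but the test leaves this open: ovule sequences under an RPKM of 5 in leaf had 0.235 times the length of the others, and the mirror ratio for leaf sequences was 0.572, short of the 0.8 it predicted. Shorter transcripts in ovule and a leaf-derived reference therefore cannot be told apart with these data.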
